A study of Homo sapiens with 12 samples.

How the data were processed

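RNA was sequenced from 12 xenograft tumours of the human cell line MCFDCIS, a breast line that forms lesions resembling ductal carcinoma in situ, grown under the skin of immunodeficient athymic nude mice. Per the labels' protocols, cells were injected, tumours were given 2 weeks to establish, palbociclib was given daily at 50 mg per kg by oral gavage, RNA was extracted from homogenised tumours with RNeasy columns, and libraries were made with a TruSeq RNA kit. The deposited values are raw counts per Ensembl gene, with human and mouse genes listed in the same file of each tumour. The submitters' processing notes name CASAVA 1.8, cutadapt, STAR and edgeR with the builds GRCh38 and GRCm38, without giving the role of each. The counting program, its strand setting, the annotation release and the way reads that fit both genomes were handled are not given in the sources used here. Antisense genes, overlapping genes and near-identical copies such as pseudogenes and histone genes are therefore uncertain, because reads could have been split or shared between them.

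Each file ended in 4 rows that name no gene. They held between 37.0% and 69.1% of all counts of a library and were left out of library sizes and tests. Gene identifiers standing on more than 1 row numbered 484, always with identical counts, and 713 repeated rows were removed. The files listed 58243 human and 54146 mouse identifiers. Symbols were found for 57980 human identifiers in GENCODE 29, which also gave the GRCh38 coordinates. The mouse identifiers were not paired with names in the tables used here, so 20 mouse gene lists written beforehand could not be tested. Counts assigned to genes came to between 8004903 and 15716211 per library.

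Samples were grouped by treatment and stage as labelled, with 3 tumours in each of 4 groups. Replicate numbers only name tumours, since the labels give no shared number across groups. Nothing in the labels says that each tumour of a group came from a different mouse, so the p-values measure the spread between these tumours. Pairs of replicates differed by more than counting noise, with chi-square per degree of freedom between 4.55 and 63.2, so no library was counted as a duplicate.

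Human and mouse genes were analysed separately in R 4.3.3 with edgeR 4.0.16, with the organism's own total as library size and trimmed mean of M-values (TMM) scaling. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 18628 human and 13055 mouse genes. All 12 libraries entered 1 quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) with 4 group means, so that the groups share 1 estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have passed. Standard errors were derived from the fold change and its F statistic. The 5 comparisons were palbociclib against vehicle at the end of treatment and after recovery, the difference between these effects, and recovery against end of treatment within each treatment. The biological coefficient of variation was 0.18 for human and 0.238 for mouse genes.

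Gene lists, 21 of them human with 574 genes of which 519 were tested, were written before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes. The same lists were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Named genes were fixed cell cycle genes, given whatever their result, up to 8 genes with the highest and 8 with the lowest fold change among genes with a symbol that passed, with a mean log2 CPM (counts scaled by library size) of at least 1 and no overlap between the groups, and the 4 members with the smallest p of each list that passed. In the other comparisons up to 5 genes per direction were taken, for the difference without the condition on overlap, and the 3 with the smallest p where none passed. Shares of counts were compared by exact two-sided permutation tests, in which 3 tumours against 3 cannot give a p below 0.1.

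The same steps were tested on simulated data drawn from each gene's mean over all libraries, its dispersion and the real library sizes. No library was simulated as standing apart. The changed genes were drawn only from those with a mean log2 CPM above 1, so the rates do not cover genes of fewer counts. For the human comparison at the end of treatment, run on 18212 genes, 65 of 100 genes changed 2-fold and 93 of 100 changed 4-fold were recovered, with 7 false calls. For the human recovery comparison, run on 18255 genes, 71 and 96 of 100 were recovered, with 8 false calls. For mouse genes 43 of 100 at 2-fold and 81 of 100 at 4-fold were recovered at the end of treatment, on 12830 genes, and 45 and 81 of 100 after recovery, on 12768 genes. In simulated lists of 30 genes, the 1 shifted list of 21 was found and 0 unshifted lists passed. These lists were random and their genes were simulated independently, whereas the real lists had estimated correlations of up to 0.82. The simulation therefore cannot tell how often the preset correlation gives false calls in the real lists.

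The alternatives were relative log expression (RLE) size factors, no composition factors, human and mouse counts together as library size, no low-count filter, a stricter filter (5 CPM in at least 3 libraries), non-robust dispersion, DESeq2 1.42.0, limma-voom with quality weights, only the groups compared, the mouse share as covariate, a 2-fold change as additional threshold, and each library left out in turn. Alternatives added after the data were seen were leaving out vehicle initial libraries 2 and 3 together (which leaves 1 vehicle initial tumour, assumed to vary like the other groups), leaving out vehicle recovery library 2 in comparisons that do not contain it, a covariate made from the share of counts in the fourth unnamed row, whose content is not given in the sources used here, and the mouse share computed without human mitochondrial genes. An alternative that drops genes with a more abundant namesake in the other organism could not be run without mouse gene names.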

Results

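Gene expression was measured by RNA sequencing in 12 xenograft tumours of the human cell line MCFDCIS, in 4 groups of 3 tumours. Tumours were collected after 2 weeks of palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, or of vehicle (the initial groups), or after the same treatments and a recovery period whose length the labels do not give (the recovery groups). Counts assigned to genes ranged from 8004903 in vehicle initial library 3 to 15716211 in palbociclib recovery library 3. Of these, 14.2% to 25.4% were assigned to mouse genes, the host part of the tumour.

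Some libraries stood apart before any comparison. Mitochondrial genes took 5.32% and 11.2% of human counts in vehicle initial libraries 2 and 3, against 0.674% to 2.64% in the other 10 libraries. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 made up most of this, with 4.61% and 10.6% of human counts. Vehicle recovery library 2 lay at 113.4 on the first principal component of human genes, which held 42.8% of the variance, while the other 11 libraries lay between -37.6 and 14.2. Its rows that name no gene held 37.0% of all counts, the lowest share of the 12 libraries.

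**Figure D1:**
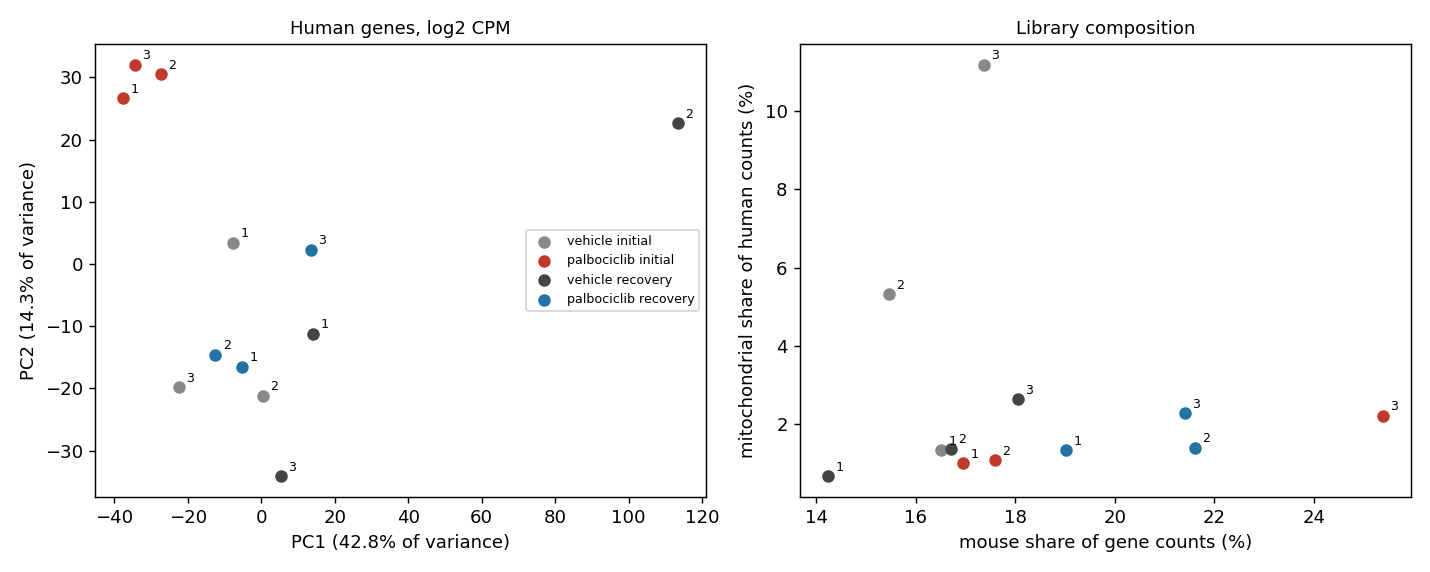
Left, the first 2 principal components of human log2 CPM for each of the 12 libraries, numbered by replicate and coloured by group; right, the mouse share of gene counts against the mitochondrial share of human counts, both in percent. Vehicle recovery library 2 lies at 113.4 on the first component, and vehicle initial libraries 2 and 3 have mitochondrial shares of 5.32% and 11.2%.

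The first comparison asked what palbociclib did to the tumour cells by the end of treatment. Genes of cell division were lower in palbociclib tumours. All 40 measured genes of the G2/M and mitosis list fell, with a median log2 fold change of -1.88, and the proliferation marker MKI67 went from 219 ± 46.2 CPM in vehicle tumours to 40.8 ± 13.9 CPM in palbociclib tumours (SD, n = 3). Genes of low oxygen response, glycolysis and several secreted chemokines and growth factors were lower too, while the D-type cyclin gene CCND1, a partner of CDK4 and CDK6, rose from 193 ± 10.3 to 333 ± 36.9 CPM (SD, n = 3). In total 343 of 18628 human genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 26 higher and 317 lower.

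Among the mitotic genes, the kinesin KIF20A had a log2 fold change of -2.55 ± 0.18 (SE, edgeR adjusted p = 1.2e-05) and the kinetochore motor CENPE one of -2.12 ± 0.17 (edgeR adjusted p = 2.5e-05). The largest falls also took in PIF1, a DNA helicase, at -3.21 ± 0.23, the centromeric histone CENPA at -2.82 ± 0.34, and TROAP at -2.74 ± 0.24. In the G1/S and DNA replication list 20 of 43 genes fell and 23 did not pass, with a median of -0.89. DTL, a substrate receptor of a ubiquitin ligase, was at -1.96 ± 0.19, UHRF1 at -1.33 ± 0.15, the ribonucleotide reductase subunit RRM2 at -1.90 ± 0.24 and the replication licensing factor CDC6 at -1.48 ± 0.21. In the homologous recombination and Fanconi anaemia list 13 of 22 genes fell, with a median of -1.06, among them EXO1 at -1.72 ± 0.20 and BARD1 at -1.12 ± 0.14. Adjusted over the list alone, 40, 42 and 15 genes of these 3 lists fell. The 3 lists passed limma's camera test at the preset correlation, and stood at adjusted p = 0.053, adjusted p = 0.064 and adjusted p = 0.10 with an estimated correlation. None of the 21 lists passed with an estimated correlation in any of the 5 comparisons. By limma's fry 6 lists passed at the end of treatment, these 3 at fry adjusted p = 0.00094, 0.0025 and 0.0038. The others were hypoxia and glycolysis, secreted factors, and sterol and fatty acid synthesis, at fry adjusted p = 0.0011, 0.023 and 0.044. KIF20A, CENPE, PIF1, CENPA, TROAP, DTL, UHRF1, RRM2, CDC6, EXO1 and BARD1 passed in each of 7 fits that left out 1 library, either any of the 6 compared or vehicle recovery library 2.

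The genes that carry the drug's target pathway gave mixed values. CCND1, on chromosome 11 from 69641087 to 69654474, rose by a log2 fold change of 0.79 ± 0.12 (SE, edgeR adjusted p = 0.002). The E-type cyclins CCNE1 and CCNE2 and the transcription factor E2F1 fell, at -1.28 ± 0.26, -1.23 ± 0.18 and -1.27 ± 0.27, and so did TOP2A, the topoisomerase of dividing cells, at -2.23 ± 0.26. CDK4, CDK6, the retinoblastoma gene RB1 and the CDK inhibitor CDKN1A did not pass, with -0.02 ± 0.27, 0.23 ± 0.18, -0.07 ± 0.16 and -0.06 ± 0.18 (edgeR adjusted p = 0.99, 0.79, 0.96 and 0.97). The signs of the values for CDK4, RB1 and CDKN1A changed under other settings. MKI67, TOP2A, CCND1 and CCNE2 passed in each of the 7 fits that left out 1 library, CCNE1 in 2 of them and E2F1 in 3. Without vehicle initial libraries 2 and 3, the libraries with the highest mitochondrial shares, 1 vehicle initial tumour remained, which was assumed to vary like the other groups. CCND1 was then at 0.87 (edgeR adjusted p = 0.093), so its value did not shrink and the call was lost with fewer tumours.

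In the hypoxia and glycolysis list 16 of 28 genes fell (24 adjusted over the list alone), with a median of -0.98. ADM, which encodes the vasodilator peptide adrenomedullin, was at -3.30 ± 0.32 (SE, edgeR adjusted p = 0.00021), the carbonic anhydrase CA9 at -2.94 ± 0.39, the enolase ENO2 at -2.66 ± 0.32, and PFKFB4, a regulator of glycolysis, at -1.89 ± 0.19, and NDRG1 was at -3.09 ± 0.42. The list had adjusted p = 0.053 with an estimated correlation, and each of these 5 genes passed in all 7 fits that left out 1 library. Of 24 secreted factors linked to senescence, 3 fell (14 adjusted over the list alone) and the median was -1.67. These were the neutrophil chemokines CXCL8, on chromosome 4 from 73740506 to 73743716, at -4.01 ± 0.63 (edgeR adjusted p = 0.0068) and CXCL1 at -3.16 ± 0.57, and the growth factor EREG at -1.64 ± 0.33. The list had adjusted p = 0.10 with an estimated correlation. Without vehicle initial libraries 2 and 3, with 1 vehicle initial tumour left, the log2 fold changes were -2.20 for CXCL8, -1.25 for CXCL1 and -1.15 for EREG (edgeR adjusted p = 0.13, 0.35 and 0.65), where both the smaller values and the fewer tumours act on the p; of the 7 fits that left out 1 library, CXCL8 passed in 6, CXCL1 in 3 and EREG in 2.

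HBEGF at -1.68 ± 0.23 and IRS2 at -1.14 ± 0.24 fell with EREG in the receptor tyrosine kinase and ligand list, of which 33 genes were measured. The list had a median of -0.13 and adjusted p = 0.38 with an estimated correlation (10 lower and 2 higher adjusted over the list alone). Its member NRG1 did not pass at 0.99 ± 0.25. HBEGF passed in all 7 fits that left out 1 library, and IRS2 in 2. Of 24 p53 targets, BTG2 and TP53INP1, both inhibitors of proliferation, rose, by 1.05 ± 0.14 and 0.67 ± 0.15, and the polymerase POLH fell, at -0.53 ± 0.13. The list's median was 0.13, with adjusted p = 0.76 with an estimated correlation, and 6 members were higher and 1 lower adjusted over the list alone. BTG2 passed in all 7 fits that left out 1 library, TP53INP1 in 1 and POLH in 1. None of 25 mesenchymal genes and none of 25 sterol and fatty acid synthesis genes passed on their own. Those lists had medians of -0.40 and -0.17, 2 and 0 members that passed adjusted over the list alone, and adjusted p = 0.76 and adjusted p = 0.29 with an estimated correlation. ZEB2 was at -3.04 ± 0.77 and FADS1 at -0.39 ± 0.12. The value of ZEB2 rested on few counts, with 0.71, 0 and 0.38 CPM in palbociclib and 1.3, 5.51 and 3 CPM in vehicle tumours. Besides BTG2, the largest rises by the rule for named genes were those of PIP, a secreted protein of apocrine tissue, on chromosome 7 from 143132077 to 143139746, at 1.83 ± 0.41 (SE, edgeR adjusted p = 0.032), the kallikrein KLK14 at 1.67 ± 0.36, ENPP2, which encodes the enzyme autotaxin, at 1.31 ± 0.25, FMO5 at 1.06 ± 0.25, INSYN2B at 0.98 ± 0.15, CNGA1 at 0.88 ± 0.20 and LIMCH1 at 0.83 ± 0.19. ENSG00000267194, which has no symbol in the annotation used, rose by 1.10 ± 0.24 (edgeR adjusted p = 0.026). Of the 7 fits that left out 1 library, INSYN2B passed in all, KLK14 in 3, PIP, ENPP2 and FMO5 in 2, and CNGA1 and LIMCH1 in 1.

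The other 12 lists did not pass at the end of treatment. Their median log2 fold changes were -0.07 for the CDK4/6-RB pathway, -0.10 for MHC class I antigen presentation, -0.02 for MYC and ribosome biogenesis, -0.06 for basal and myoepithelial genes, 0.10 for the human copies of host cell genes, 0.03 for interferon-stimulated genes, 0.03 for keratinisation, 0.01 for luminal genes, 0.12 for lysosome genes, -0.47 for the mitochondrial genome, -0.02 for oxidative phosphorylation and 0.12 for the unfolded protein response. Camera's direction was opposite to the median for basal, interferon-stimulated and keratinisation genes. Among members of these lists KRT5, TAGLN and MYLK of the basal list rose, as did CCND1, while RBL1 of the CDK4/6-RB list and OAS3 of the interferon list fell. The count of 343 genes was 160 and 173 without palbociclib initial libraries 1 and 3, 196 without vehicle initial library 2, 95 without vehicle initial libraries 2 and 3, all of them lower and with 1 vehicle initial tumour left, and 748 (169 higher, 579 lower) without vehicle recovery library 2. It was 147 with the mouse share as covariate and 213 with the share of the fourth unnamed row as covariate, a share of 14.21% ± 1.94 in palbociclib and 28.34% ± 11.96 in vehicle tumours (SD, n = 3; exact permutation p = 0.1, the smallest possible).

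**Figure D2:**
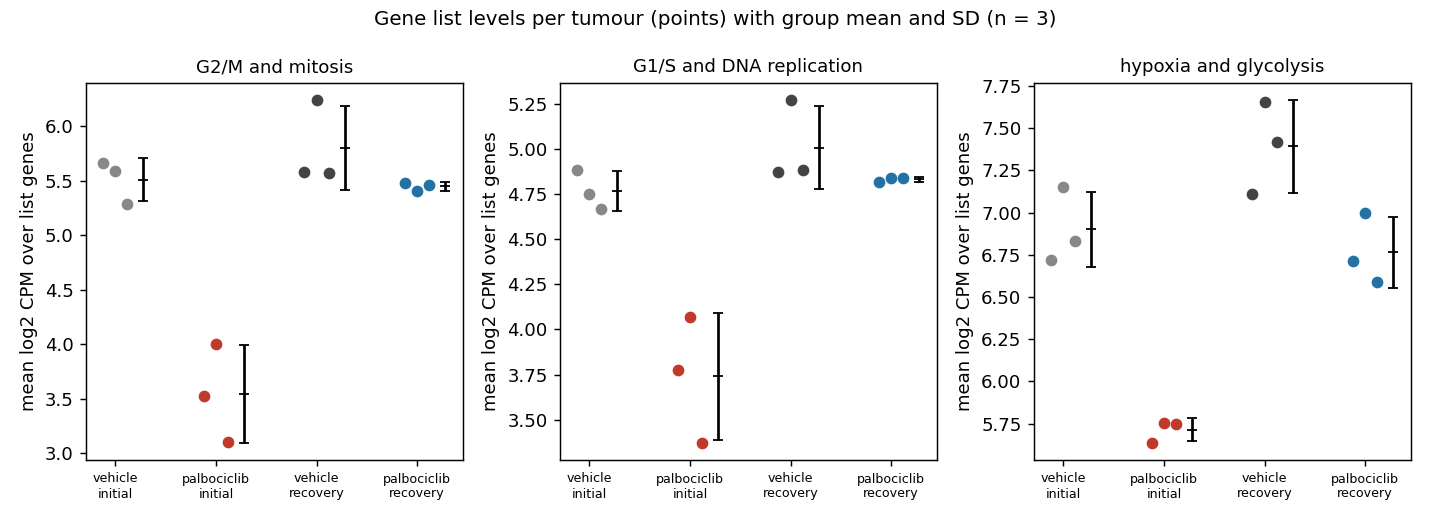
Mean log2 CPM over the genes of 3 lists (vertical axes, which do not start at 0) in each tumour, by group, with the group mean and SD (n = 3) beside the points. All 3 palbociclib initial tumours lie below all other tumours in each list.

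The recovery comparison asked what remained of the drug effect after the recovery period. None of the fixed cell cycle genes passed. MKI67 was at 183 ± 4.27 CPM in palbociclib recovery and 223 ± 38.6 CPM in vehicle recovery tumours (SD, n = 3), a log2 fold change of -0.29 ± 0.21 (SE, edgeR adjusted p = 0.65). TOP2A was at -0.34 ± 0.25, CCND1 at -0.02 ± 0.12, CCNE1 at -0.35 ± 0.23, CCNE2 at 0.08 ± 0.17, E2F1 at 0.01 ± 0.25, CDK4 at -0.35 ± 0.26, CDK6 at -0.34 ± 0.18, RB1 at -0.33 ± 0.16 and CDKN1A at 0.00 ± 0.18. By edgeR 1 of 18628 genes passed, TUBBP6, a processed pseudogene of a tubulin gene on chromosome 7 from 55645620 to 55646951. It was at 0.49 ± 0.0843 CPM in palbociclib and 3.82 ± 0.976 CPM in vehicle tumours (SD, n = 3), a log2 fold change of -2.93 ± 0.35 (SE, edgeR adjusted p = 0.017). As a processed pseudogene it is uncertain, because the handling of reads shared with tubulin genes is not given in the sources used here.

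The next smallest p-values belonged to the pseudogene AC091812.1 at -2.84 ± 0.43, which also lies on chromosome 7, from 55656768 to 55678490, and to the cholesterol exporter ABCA1 at -1.61 ± 0.30, neither of which passed (edgeR adjusted p = 0.11 and 0.55) and both of which were chosen after their values were seen. DESeq2 called 18 genes, all lower, and 1613 genes had an unadjusted edgeR p under 0.05. TUBBP6 did not pass without any 1 of palbociclib recovery libraries 1, 2 and 3 or vehicle recovery library 1, nor with the mouse share or the fourth unnamed row share as covariate, nor with only the groups compared (edgeR adjusted p = 0.72). The stricter low-count filter left it untested and gave 0 genes.

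At the preset correlation 16 of 21 lists passed after recovery, 15 lower and 1 higher, although no member of any list passed on its own. The hypoxia and glycolysis list had a median of -0.53 and all 28 members had negative values, with 19 lower adjusted over the list alone, ENO2 at -1.25 ± 0.28, SLC2A1 at -0.88 ± 0.21 and CA9 at -1.27 ± 0.32. It had adjusted p = 0.37 with an estimated correlation, a value no list went below. The mesenchymal list had a median of -0.76, with MMP2 at -1.15 ± 0.27 and COL6A1 at -1.78 ± 0.42, 14 members lower and 1 higher adjusted over the list alone, and adjusted p = 0.37 with an estimated correlation. The G2/M list was at a median of -0.39, secreted factors at -0.62, interferon-stimulated genes at -0.32, with adjusted p = 0.56, adjusted p = 0.39 and adjusted p = 0.37 with an estimated correlation. Luminal genes were at 0.39, with FOXA1 at 0.96 ± 0.27, and adjusted p = 0.56 with an estimated correlation. Medians of the other lists that passed were -0.16 for the CDK4/6-RB pathway, with CDKN2C at -0.57 ± 0.29 and SKP2 at -0.34 ± 0.21, -0.19 for G1/S, -0.23 for MHC class I, with HLA-B at -0.85 ± 0.21, -0.11 for MYC and ribosome biogenesis, with FBL at -0.59 ± 0.30 and SRM at -0.55 ± 0.32, -0.27 for basal, -0.21 for homologous recombination, -0.14 for lysosome, -0.44 for the mitochondrial genome, -0.09 for oxidative phosphorylation and -0.21 for receptor tyrosine kinases, with adjusted p between 0.39 and 0.59 with an estimated correlation. Adjusted over the list alone, 2 genes of the receptor tyrosine kinase and ligand list and 1 MHC class I gene were lower. No gene of the other lists just named passed that way. The lists that did not pass had medians of 0.31 for human copies of host cell genes, 0.27 for keratinisation, -0.09 for p53 targets, 0.08 for sterol synthesis and -0.05 for the unfolded protein response. Vehicle recovery library 2 had the highest mean level of all 12 libraries in each of the 15 lists that were lower, and the lowest in the luminal list. Without it 8 lists passed, and the medians were -0.36 for hypoxia, -0.29 for mesenchymal genes, -0.12 for G2/M, -0.42 for secreted factors, -0.17 for interferon-stimulated genes, 0.11 for luminal genes, -0.14 for receptor tyrosine kinases, -0.14 for basal, -0.10 for the mitochondrial genome and -0.05 for MHC class I. The medians of the other 6 lists that had passed then lay between -0.03 and 0.05. FOXA1 was at 0.66, HLA-B at -0.50, MMP2 at -0.69 and COL6A1 at -1.05 without that library, and CDKN2C, SKP2, FBL and SRM turned slightly positive. Without vehicle recovery library 3 medians were -0.29 for the CDK4/6-RB pathway, -0.31 for G1/S, -0.35 for MHC class I, -0.19 for MYC, -0.46 for basal, -0.25 for lysosome, -0.18 for oxidative phosphorylation and -0.37 for receptor tyrosine kinases. They were -0.25 for MYC, -0.67 for the mitochondrial genome and -0.15 for oxidative phosphorylation without vehicle recovery library 1, and -0.37 for MHC class I, -0.50 for basal and -0.32 for receptor tyrosine kinases without palbociclib recovery library 3. The basal median was -0.11 without palbociclib recovery library 2, and that of lysosome genes -0.09 without palbociclib recovery library 1.

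No gene passed in the same direction at both stages, where independent calls would share 0.017 and DESeq2's calls shared 2. With 1 gene called after recovery the edgeR overlap could be at most 1, so it cannot decide whether effects carried over. The 317 genes lower at the end of treatment had a median log2 fold change of -0.27 after recovery, and 292 had negative values (limma's fry, adjusted p = 0.10). The 26 genes higher at the end of treatment had a median of 0.17 after recovery, and 19 had positive values (fry adjusted p = 0.011), with adjusted p = 0.082 by camera with an estimated correlation. Without vehicle recovery library 2 these medians were -0.10 and 0.18 (fry adjusted p = 0.35 and adjusted p = 0.038).

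**Figure D3:**
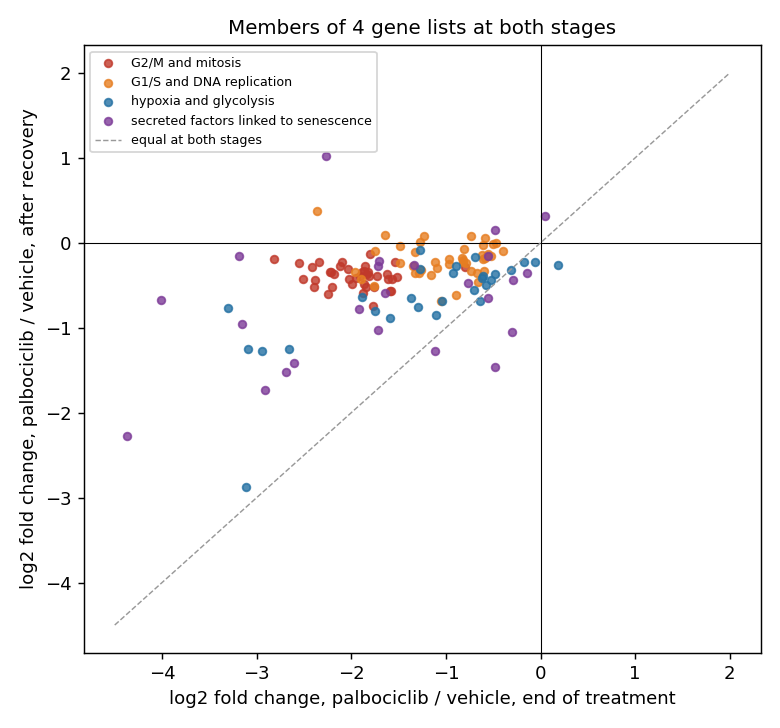
Each point is a gene of 1 of 4 lists, with its log2 fold change of palbociclib over vehicle at the end of treatment (horizontal) and after recovery (vertical); the dashed line marks equal values. Members of the G2/M list have a median of -1.88 at the end of treatment and of -0.39 after recovery.

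The difference between the effects was also tested directly. It passed for 41 genes, all with a higher signed log2 fold change of palbociclib over vehicle after recovery than at the end of treatment. These 41 genes had negative values at the end of treatment, with a median of -2.06, and values nearer 0 after recovery, with a median of -0.19. PIF1 was at a difference of 2.92 ± 0.29 (SE, edgeR adjusted p = 0.001), TROAP at 2.75 ± 0.31, the atypical E2F factor E2F8 at 2.73 ± 0.49, CENPA at 2.63 ± 0.44 and ADM at 2.53 ± 0.42. In the G2/M list 11 of 40 members passed (39 adjusted over the list alone), with a median difference of 1.54, and in the G1/S list 4 of 43 (21 adjusted over the list alone), with a median of 0.72. In the hypoxia and glycolysis list ADM was the 1 gene of 28 that passed (10 adjusted over the list alone), with a median of 0.43 and adjusted p = 0.39 with an estimated correlation. At the preset correlation 14 of 21 lists passed, 7 higher and 7 lower, and none did with an estimated correlation, where the G2/M list had adjusted p = 0.22 with an estimated correlation. Without vehicle recovery library 2 the lists that passed numbered 6. PIF1 and TROAP passed in all 12 fits that left out 1 library, ADM in 4, and E2F8 and CENPA in 2. The count of 41 genes moved by over 1.5 times whichever of the 12 libraries was left out. It was 12, 70 and 19 without palbociclib initial libraries 1, 2 and 3, 15, 14 and 22 without palbociclib recovery libraries 1, 2 and 3, 20, 14 and 17 without vehicle initial libraries 1, 2 and 3, and 17, 161 and 21 without vehicle recovery libraries 1, 2 and 3. It was 4 without vehicle initial libraries 2 and 3, with 1 vehicle initial tumour left, and 14 with the fourth unnamed row share as covariate.

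Comparing the stages within palbociclib tumours, cell division genes rose from the end of treatment to recovery. All 40 G2/M genes and 27 of 43 G1/S genes rose, with medians of 1.88 and 0.94, and 18 of 28 hypoxia and glycolysis genes rose, with a median of 0.85. CXCL8 rose by 3.38 ± 0.63 (SE, edgeR adjusted p = 0.016), ADM by 3.33 ± 0.32, the chemokine CCL20 by 3.17 ± 0.74, PIF1 by 3.04 ± 0.23 and TMCC3 by 2.98 ± 0.68. In the palbociclib initial tumours few counts stood behind CCL20 (0.53, 0.51 and 0.19 CPM) and TMCC3 (0.62, 0.31 and 0.48 CPM). PIP fell, at -2.33 ± 0.41, as did OLFM4 at -1.94 ± 0.46, the growth factor NRG1 at -1.91 ± 0.26, the water channel AQP1 at -1.83 ± 0.34 and RBM20 at -1.73 ± 0.31. These falling genes were also lower in every vehicle recovery tumour than in any vehicle initial tumour, although none passed there. AQP1, for example, went from 46.05, 22.4 and 29.33 to 7.5, 3.36 and 12.06 CPM. The falls therefore cannot be told apart from change with tumour age. Medians between vehicle stages were 0.28 for G2/M, 0.25 for G1/S and 0.49 for hypoxia genes. In total 526 genes passed by edgeR, 439 higher and 87 lower.

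At the preset correlation 7 lists rose between the palbociclib stages. Besides G2/M, G1/S and hypoxia genes (40, 43 and 24 higher adjusted over the list alone), 11 of 22 homologous recombination genes rose, with a median of 0.99, 7 of 24 secreted factors, with a median of 1.58, 4 of 26 keratinisation genes, with a median of 0.53, and 2 of 25 sterol synthesis genes, with a median of 0.26. Adjusted over the list alone, 14, 12, 9 and 7 members of these 4 lists were higher. G2/M, G1/S, hypoxia and sterol lists had adjusted p = 0.059 with an estimated correlation, and the other 3 had adjusted p = 0.12, adjusted p = 0.095 and adjusted p = 0.080 with an estimated correlation. By fry the same 7 lists passed, with fry adjusted p between 0.0012 and 0.013. ADM, PIF1, PIP, NRG1 and RBM20 passed in each of 7 fits that left out 1 library, CXCL8 in 5, AQP1 in 3, TMCC3 in 2, and CCL20 and OLFM4 in 1. These palbociclib initial libraries also served the comparison at the end of treatment. The count of 526 was 205, 349 and 233 without palbociclib initial libraries 1, 2 and 3, 280, 266 and 315 without palbociclib recovery libraries 1, 2 and 3, and 1425 (979 higher, 446 lower) without vehicle recovery library 2. The balance of directions also moved with limma-voom, which gave 1418 higher and 894 lower, and with only the groups compared, which gave 1083 higher and 533 lower.

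Between the stages of vehicle tumours no human gene passed by edgeR. The smallest p-values belonged to INSYN2B at -1.24 ± 0.17, the neurotrophin receptor NTRK2 at -1.27 ± 0.21 and the non-coding LINC02006 at -2.39 ± 0.40 (edgeR adjusted p = 0.053, 0.16 and 0.16). An unadjusted edgeR p under 0.05 was reached by 2688 genes, and DESeq2 called 81 and limma-voom 11. At the preset correlation 15 lists passed, all higher after recovery. Hypoxia and glycolysis had the smallest p by camera and a median of 0.49. It had adjusted p = 0.34 with an estimated correlation, a value that other lists shared. The medians of secreted factors and mesenchymal genes were larger, at 0.76 and 0.67. No list member passed on its own. Adjusted over the list alone, 15 hypoxia, 6 lysosome, 5 MHC class I and 1 basal genes were higher. In the receptor tyrosine kinase and ligand list 2 genes were higher and 1 was lower that way. Without vehicle recovery library 2, which had the highest mean level in 14 of these 15 lists, 9 lists passed. The edgeR count was 3, 6 and 4 without vehicle initial library 2, vehicle recovery library 1 and vehicle recovery library 2.

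The mouse genes reported on the host tissue of the tumours. Their share of gene counts was 19.98% ± 4.69 in palbociclib and 16.4% ± 0.96 in vehicle tumours at the end of treatment (SD, n = 3; exact two-sided permutation p = 0.2), and 20.7% ± 1.44 against 16.3% ± 1.93 after recovery (SD, n = 3; exact permutation p = 0.1, the smallest possible). Of 13055 mouse genes edgeR called 0 for palbociclib at the end of treatment, after recovery and for the difference, and 0 between vehicle stages. Unadjusted edgeR p under 0.05 was reached by 1024, 940, 696 and 1267 genes, DESeq2 called 39, 37, 1 and 14, and limma-voom called 0, 1, 0 and 0. Between the palbociclib stages 3 genes passed: ENSMUSG00000021775 fell from 99.2 ± 16.1 to 33.5 ± 3.04 CPM, ENSMUSG00000020889 fell from 38.9 ± 6.74 to 10.8 ± 5.22 CPM, and ENSMUSG00000029641 rose from 6.61 ± 3.88 to 30.6 ± 6.88 CPM (SD, n = 3). At the end of treatment, 62 mouse genes passed without vehicle initial library 1 and 1 without palbociclib initial library 1. After recovery, 5 passed without palbociclib recovery library 3, and 1 without vehicle recovery library 1 or 2. For the difference, 1 passed without palbociclib initial library 1 or vehicle recovery library 3, and between vehicle stages 16 passed without vehicle initial library 2 and 1 without vehicle recovery library 3. The 3 genes became 1 without palbociclib initial library 2 or 3, and 0 without palbociclib recovery library 2. The mouse identifiers were not paired with gene names in the tables used here.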

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

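The tests of library composition and the sorting of splits by the stage they mixed were chosen after the results were seen, and the splits of the libraries were set beforehand. The results in this part were singled out because the palbociclib effect differed between the stages by a test of the difference itself. That test passed for 41 human genes and for 14 gene lists at the preset correlation. All 41 genes had negative values at the end of treatment, with a median log2 fold change of -2.06, and values nearer 0 after recovery, with a median of -0.19. The genes named by rule differed by 2.92 for PIF1, 2.75 for TROAP, 2.73 for E2F8, 2.63 for CENPA and 2.53 for ADM on the log2 scale. Among 40 splits of the libraries drawn within the stages, the real one included, 6 gave as many genes as the real 41, and the highest other split gave 226, while PIF1 and TROAP passed in all 12 fits that left out 1 library, ADM in 4, and E2F8 and CENPA in 2. All 5 other splits with at least 41 genes kept the treatment groups at the end of treatment and mixed them after recovery, so they carried the effect at the end of treatment, while the 32 splits that mixed the groups at the end of treatment gave at most 1. The share of 6 in 40 therefore does not decide whether chance is excluded for this count. The high counts point to a structure of the samples that includes the treatment groups at the end of treatment.

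For the comparisons of 3 tumours with 3, the 10 possible splits are too few for a share under 0.05. At the end of treatment 1 of 10 splits, the real one, gave as many as 343 human genes, and the highest other gave 0. For the palbociclib stages 1 of 10 gave as many as 526, and the highest other gave 0. After recovery 2 of 10 gave as many as the real 1, and the highest other gave 4; between vehicle stages all 10 gave the real 0, and the highest other was 0. For mouse genes, all 10 splits gave at least the real 0 at the end of treatment, after recovery and between vehicle stages, with highest others of 2, 0 and 0. Between the palbociclib stages 1 of 10 splits gave as many as the real 3 mouse genes, and the highest other gave 1. For the difference in mouse genes all 40 splits gave at least the real 0, and the highest other gave 1.

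The 317 human genes lower in palbociclib tumours at the end of treatment were set against library composition. If low residual ribosomal and mitochondrial RNA, for which the fourth unnamed row may stand, set their level, recovery libraries with an equally low share in the fourth unnamed row would be as low, but the lowest of those 4 libraries lay 1.11 log2 CPM above the highest palbociclib initial library, where the SD of the palbociclib initial libraries was 0.26. If the host share set it, recovery libraries with as high a mouse share would be as low, but the lowest of those 4 lay 1.05 above. Both values argue against these as the whole cause. The genes were chosen for being low in the palbociclib initial libraries, so that choice may have widened both gaps. All 317 genes stayed negative with either share as covariate. Their median log2 fold change went from -1.31 (median SE 0.21) to -1.48 (median SE 0.27) with the fourth unnamed row share, where 200 passed and the calls were lost with larger SEs in all 317 genes. With the mouse share it went to -1.19 (median SE 0.24), where 137 passed, 258 genes lay nearer 0 and 293 had larger SEs, so a small contribution of the host share stays open. Palbociclib treatment, which the design names, remains open as a hypothesis.

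Vehicle recovery library 2 stood apart on the first principal component. Its non-coding genes deviated from the other vehicle recovery libraries by a median of -0.79 log2 CPM, against 0.15 for coding genes. A smaller share of non-coding transcripts alone would leave coding mesenchymal genes with the rest, but these exceeded the median coding gene by 0.81, more than in any other library, where the highest excess was 0.55. The mesenchymal list was picked after the results were seen. It was 1 of the 15 lists lower after recovery, in each of which this library had the highest mean level. That choice may have widened the excess. Its mouse share of 16.7% and its human mitochondrial share of 1.37% lay inside the range of the other 11 libraries, which argues against host reads and mitochondrial RNA. No biological explanation was tested.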

How the results depend on the processing

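The alternatives that leave out vehicle initial libraries 2 and 3 together, or vehicle recovery library 2 where it was not compared, and the covariate of the fourth unnamed row were chosen after seeing the data. Without vehicle initial libraries 2 and 3, 1 vehicle initial tumour remained, assumed to vary like the other groups, so a call lost there does not by itself show a weaker effect. Of the counts and shares under alternatives, 178 stayed within 1.5 times of the reported value or kept their direction, and 108 did not. Of the values of named genes 2403 kept direction and side of the threshold, 223 lost their call, 85 gained 1 and 38 reversed. Of the list values 560 were kept, 184 lost the call and 4 reversed. No paired analysis was possible because the labels give no shared replicate numbers. Genes of few counts are measured least precisely, and 2-fold changes of mouse genes were recovered in 43 of 100 simulated cases at the end of treatment.

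For palbociclib at the end of treatment the 343 human genes became 931 with limma-voom (208 higher, 723 lower), 753 without a low-count filter, 689 with only the groups compared (155 higher, 534 lower), 147 with the mouse share and 213 with the fourth unnamed row share as covariate, 95 without vehicle initial libraries 2 and 3, and 160 to 748 with 1 library left out. After recovery the 1 gene became 18 with DESeq2, 2 with limma-voom, 794 without a filter (212 higher, 582 lower), 2 with human and mouse counts as library size, 0 with the stricter filter, only the groups compared, or either covariate, and 0 to 1 with 1 library left out. Of the 794 genes, 780 were also tested with the filter, so few of the calls were added genes; how the added genes changed the fit was not tested. The 41 genes of the difference became 91 with DESeq2, 246 with limma-voom, 320 without a filter (222 higher, 98 lower), 22 with joint library size, 14 with the fourth unnamed row share, 4 without vehicle initial libraries 2 and 3 (fewer samples), and 12 to 161 with 1 library left out. Between vehicle stages 0 became 1 with RLE factors, 81 with DESeq2 (47 higher, 34 lower), 11 with limma-voom (5 higher, 6 lower), 1124 without a filter (837 higher, 287 lower) and 0 to 6 with 1 library left out. Between palbociclib stages 526 (439 higher, 87 lower) became 2312 with limma-voom (1418 higher, 894 lower), 1147 without a filter, 1616 with only the groups compared (1083 higher, 533 lower), 350 with joint library size, 299 with a 2-fold change required, and 205 to 1425 with 1 library left out. The overlap of 0 became 2 with DESeq2. Except where stated, the cause was not tested.

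For mouse genes the 0 at the end of treatment became 39 with DESeq2, 288 without a filter, 1 with joint library size, 1 with the fourth unnamed row share and 0 to 62 with 1 library left out. After recovery 0 became 37 with DESeq2, 1 with limma-voom, 159 without a filter, 15 with only the groups compared, 19 with joint library size, all higher, 1 with the mouse share, 4 with the fourth unnamed row share and 0 to 5 with 1 library left out. The difference gave 1 with DESeq2, 73 without a filter, 1 without vehicle initial libraries 2 and 3, and 0 to 1 with 1 left out. Between vehicle stages 0 became 14 with DESeq2, 211 without a filter, 34 without vehicle initial libraries 2 and 3, and 0 to 16 with 1 left out. Between palbociclib stages 3 genes, 1 of them higher, became 21 with DESeq2 (13 higher, 8 lower), 5 with limma-voom, 164 without a filter (114 higher, 50 lower), 1 with non-robust dispersion, 9 with only the groups compared, 1 with the fourth unnamed row share, 2 without composition factors (1 higher, 1 lower), 4 with joint library size (2 higher, 2 lower) and 0 to 3 with 1 left out. Joint library size moved the median of all genes by -0.108 for human genes after recovery and by 0.206 and 0.286 for mouse genes at the end of treatment and after recovery. The causes were not tested.

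With an estimated correlation 0 lists passed in each of the 5 comparisons, where 9, 16, 14, 15 and 7 had passed. With fry, 6 passed at the end of treatment, 0 after recovery, 1 for the difference, 0 between vehicle stages and 7 between palbociclib stages. With the fourth unnamed row share as covariate 8 passed for the difference and 9 between vehicle stages. With 1 library left out the number ranged from 8 to 17 after recovery, from 6 to 16 for the difference and from 9 to 18 between vehicle stages. Among lists, secreted factors in the difference reversed to a median of -0.21 without vehicle initial libraries 2 and 3. With 1 library left out the medians ranged from -0.25 to 0.05 for MYC and ribosome biogenesis and from -0.18 to 0.03 for oxidative phosphorylation after recovery, and from -0.02 to 0.31 for p53 targets between vehicle stages.

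Named genes that reversed were mostly near 0. At the end of treatment CDK4 was at 0.03 without composition factors, 0.10 with limma-voom, 0.04 with the mouse share and -0.15 to 0.18 with 1 library left out; RB1 was at 0.01 without vehicle initial libraries 2 and 3. CDKN1A was at 0.01 without composition factors and with the mouse share, 0.15 without vehicle initial libraries 2 and 3, 0.06 with the fourth unnamed row share and -0.15 to 0.12 with 1 left out. After recovery CDK4 was at 0.05 with limma-voom and -0.55 to 0.12 with 1 left out, and CCND1 at 0.05 without composition factors, 0.02 with the stricter filter and -0.12 to 0.04 with 1 left out. CCNE2 was at -0.03 with joint library size, and TOP2A at 0.02 with the mouse share. CDKN1A was at -0.02 with RLE factors, -0.03 with DESeq2 and the fourth unnamed row share, -0.10 with joint library size and -0.18 to 0.14 with 1 left out. E2F1 was at -0.01 with RLE factors, -0.02 with DESeq2, -0.09 with limma-voom, -0.10 with joint library size and -0.08 to 0.08 with 1 left out. SRM was at 0.06 with limma-voom and -0.79 to 0.09 with 1 left out. CDKN2C ranged from -0.81 to 0.03, SKP2 from -0.55 to 0.03 and FBL from -0.82 to 0.01 with 1 left out, each turning without vehicle recovery library 2. The causes were not tested.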

Other observations

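The histone, immediate early and metallothionein groups, and the second check of clock genes, were chosen after the main results were seen. Their p-values come from the same libraries and do not allow for this choice. Histone genes were lower at the end of palbociclib treatment: 32 of 52 measured histone genes fell, 50 had negative values and the median log2 fold change was -1.14 (limma's fry, adjusted p = 0.0096 over 25 tests), with adjusted p = 0.093 by camera with an estimated correlation. HIST1H1A was at -1.38 ± 0.20 and HIST1H4A at -1.56 ± 0.23 (SE, edgeR adjusted p = 0.0018 and 0.0017), and histone genes are uncertain as near-identical copies. Of 16 immediate early genes, which respond within minutes to growth signals and stress, 4 fell: FOS at -1.18 ± 0.15, JUN at -0.89 ± 0.13, KLF4 at -1.35 ± 0.31 and PPP1R15A at -1.39 ± 0.16 (edgeR adjusted p = 0.00046, 0.002, 0.04 and 0.00025). Their median was -0.47 (fry adjusted p = 0.0016), with adjusted p = 0.036 by camera with an estimated correlation. Without vehicle initial libraries 2 and 3, with 1 vehicle initial tumour left, the medians were -1.41 for histone genes and -0.57 for immediate early genes, and 4 and 2 members passed. After recovery the medians were -0.25 and -0.03, and 0 members of either group passed by edgeR; without vehicle recovery library 2 they were 0.02 and 0.04.

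The metal-binding metallothioneins had negative values at both stages. The 4 measured genes had a median of -1.05 at the end of treatment (fry adjusted p = 0.0096) and of -1.46 after recovery (fry adjusted p = 0.0042), with adjusted p = 0.080 and adjusted p = 0.036 by camera with an estimated correlation. By edgeR 0 of them passed on their own at either stage. MT2A was at -1.83 ± 0.42 at the end of treatment and MT1X at -1.04 ± 0.25 (edgeR adjusted p = 0.056 for both). The median after recovery was -1.15 without vehicle recovery library 2 and that at the end of treatment -1.10 without vehicle initial libraries 2 and 3.

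A difference in the time of day of collection was set up as a hypothesis for the palbociclib stages, with 15 human clock genes signed by their known phase, before their values were seen. The prediction, a p under 0.05 with the arms at medians of opposite sign, was met: limma's fry gave a p of 0.011, the 10 genes of the D-box and REV-ERB arm, DBP and PER3 among them, had a median of -0.06, and the 5 genes of the BMAL1 arm one of 0.19. Tested alone, the D-box and REV-ERB arm had fry adjusted p = 0.64 and the BMAL1 arm fry adjusted p = 0.018. By camera with an estimated correlation they had adjusted p = 0.77 and adjusted p = 0.19. The size was small, with a signed median of -0.08, and the signed score per tumour differed by -0.12 (exact two-sided permutation p = 0.1, the smallest possible). NFIL3, at 0.96 ± 0.18 (edgeR adjusted p = 0.0081), was the gene that passed, and fry gave a p of 0.12 without it. In palbociclib against vehicle tumours at the end of treatment, outside the prediction, the D-box and REV-ERB arm had a median of -0.18 with 9 of 10 values negative (fry adjusted p = 0.037 over 25 tests; adjusted p = 0.17 by camera with an estimated correlation), and 0 of its genes passed by edgeR. The BMAL1 arm was at -0.06 there (fry adjusted p = 0.45), with the same sign, so the tests of human genes leave the hypothesis open. The 3 mouse genes that passed between the palbociclib stages had no names here. Whether host clock genes are among them was not checked.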
